A study of Mus musculus with 18 samples.

How the data were processed

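RNA was profiled in microglia from mouse embryos of the C57BL/6 background at E17.5, with the sex recorded as unknown in the labels. Per the labels' protocols, hippocampi were pooled and dissociated with trypsin and DNase, and cells carrying GFP at the Cx3cr1 locus were sorted by FACS. RNA was extracted with a miRNeasy kit and amplified and labelled with Ovation Pico WTA v2 and Encore Biotin kits. It was then hybridized to Affymetrix Mouse430_2 arrays. Per the series' design text, RNA was pooled per pregnant dam, so that an array stands for the pooled embryos of a dam and the arrays were taken as independent replicates.

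The values deposited by the authors are log2 expression values for 45101 probe sets on 18 arrays. RMA, which corrects background, normalizes arrays and summarizes the probes of a probe set, is named in the submitters' processing notes. Its version, its variant and whether all arrays were processed together are not given in the sources used here. All arrays share a lowest log2 value of 2.19, and the values show no centring per gene. The columns were used as deposited. The raw intensities were not used here. For arrays, their number limits the precision.

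Groups were taken from the labels: 4 LPS, 4 PBS, 4 DAP12KO and 6 untreated wild-type (UT) arrays. The year in each label was treated as a batch, numbered 1 to 4 in order of time. Whether these years mark hybridization, sorting or something else is not given in the sources used here. Each batch with LPS arrays held as many PBS arrays. In batch 2 the LPS and PBS arrays of the same replicate number deviated alike from their group means (Pearson r = 0.53 over genes). They may therefore not be independent. For DAP12KO and UT arrays of the same number r was −0.01 and 0.01. The main fit takes no account of the likeness in batch 2, and a block by replicate number was tried beside it. Over probe sets the LPS arrays of batch 2 (Pearson r = 0.984) and the PBS arrays of batch 2 (0.980) were also the most alike of all pairs. These PBS arrays had r of 0.866 to 0.919 with the other PBS arrays. Whether the arrays of such a pair are fully independent was not tested. The DAP12KO arrays were all in batch 4, so that with the batch term the UT arrays of batch 4 set the difference and those of batch 3 added to the estimate of the spread only.

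Of the probe sets, 34958 named exactly 1 gene symbol, 932 named several and 9211 named none. The first of these were used, and 34754 of them had an Entrez identifier in the RefSeq gene table, with 0 symbols updated. They named 18194 genes. Each gene was represented by its probe set with the highest mean over the 18 arrays. Genes whose probe set had a mean under the 40th percentile of all probe sets (log2 2.49) were left out, which left 11630 genes. A value under that threshold is called near the floor, and 22.4% of the tested genes had such a value on 1 or more arrays. A fold against a group with all arrays near the floor was computed against this threshold and is given as a lower bound.

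All 18 arrays were fitted together with limma 3.58.1 in R 4.3.3, with a mean per group and batch as an additive term (residual degrees of freedom 11). The moderated test used a variance prior that follows intensity. The contrasts were LPS minus PBS, DAP12KO minus UT, and the difference between these responses. All tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes within a contrast and a threshold of 0.05. Errors of log2 differences are standard errors of the fit, and errors of group means are standard deviations over arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

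A total of 40 gene lists covered markers of microglia and of other cells that the sort could hold, sex-linked genes, immune pathways, neural gene groups, the cell cycle, stress and metabolism. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the 40 lists within a contrast. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move one way on balance and compares the list with no other genes. Of the names on the lists, 77 had no probe set of their own on the array. Some genes stand on several lists, among them Itgam, Trem2, Ccl4, Csf1r, Dcx, Stmn2, Gap43, Mapt, Syt1, Snap25 and Reln.

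Named genes followed a fixed rule. Those past the threshold with all arrays on 1 side of the control mean of their batch were named, up to 12 per direction. Pcsk5 counted as lower although in batch 1 its LPS and PBS values were equal at the floor. Where fewer than 6 passed, the 5 with the lowest p in each direction were named as not passed. The 4 members with the lowest p of each described list were added, with Tyrobp, Trem2, Cx3cr1, Csf1r, Aif1, Itgam, P2ry12, Il1b and Tnf in both comparisons, and the 5 lowest p in each direction for the difference of the responses. Predicted and clone names were skipped in the first and the last of these parts.

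The groups, the batches, the model, the filter, the lists, the naming rule and most of the other settings tried were fixed before the data were examined. These settings were other batch terms, a block by replicate number, fewer groups or batches, other filters and probe set rules, added normalization, other variance models, array weights, the Gapdh 3′ minus 5′ difference as a covariate, each array left out in turn, and a plain test per gene without shared variance. Chosen after seeing the data were fits without the 2 PBS arrays of batch 2, without batch 2, with the neuron marker mean of each array as a covariate, and with values under log2 4 set to 4.

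The fit was tested on simulated data with the same groups and batches. Of genes given a true log2 change of 1, 2 and 3, the LPS contrast recovered 6.06%, 31.3% and 61.2%, and the DAP12KO contrast recovered 0%, 34.3% and 56.7%, with 5 false calls in each. A simulated list shifted by log2 0.7 had a camera p of 1.3e-06 and 8.12e-06 in these contrasts, and an unshifted list had 0.346 and 0.327. The simulated noise was independent between genes and the list members were drawn at random. The simulation therefore cannot show how camera at the preset correlation behaves for lists whose members vary together.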

Results

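Gene expression was measured in microglia, the resident immune cells of the brain, sorted from the hippocampi of mouse embryos at E17.5. Of the 18 arrays, 4 came from embryos of dams given lipopolysaccharide (LPS, a bacterial endotoxin that triggers inflammation) and 4 from dams given PBS. A further 4 came from embryos lacking DAP12 (DAP12KO) and 6 from untreated wild-type embryos (UT). DAP12, encoded by Tyrobp, is an adaptor protein that carries the signals of receptors such as TREM2. Batch 1 held 1 LPS and 1 PBS array, batch 2 held 2 of each, batch 3 held 2 UT arrays, and batch 4 held 1 LPS, 1 PBS, 4 DAP12KO and 4 UT arrays. The median log2 value of an array lay between 2.78 and 3.17, and 32.8% to 38.2% of its probe sets stood at the lowest value of 2.19.

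Microglia genes were bright throughout. The mean of 28 microglia identity genes, such as Cx3cr1, P2ry12 and Csf1r, lay between 12.13 and 13.07 in 16 arrays, and at 11.04 and 11.10 in the 2 PBS arrays of batch 2. Those 2 arrays also held the highest means of 23 neuron markers (11.08 and 11.16, against 6.27 to 9.48 elsewhere) and of 17 neural progenitor and radial glia markers (10.78 and 10.86, against at most 8.82). Choroid plexus markers (2 of the 10 written members tested) reached 8.72 and 10.07 there, against at most 7.19 in the other arrays. Of 9 neural, vascular and stromal marker lists, with 2 to 23 tested members each, 8 had their 2 highest means in these arrays, the exception being endothelial markers. The Gapdh 3′ minus 5′ difference, a measure of RNA integrity in which higher values mean a stronger bias to the 3′ end, was 2.01 to 3.33 in batches 1 and 2. In batch 4 it was 0.89 to 1.2, apart from UT replicate 2 at 2.23.

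**Figure D1:**
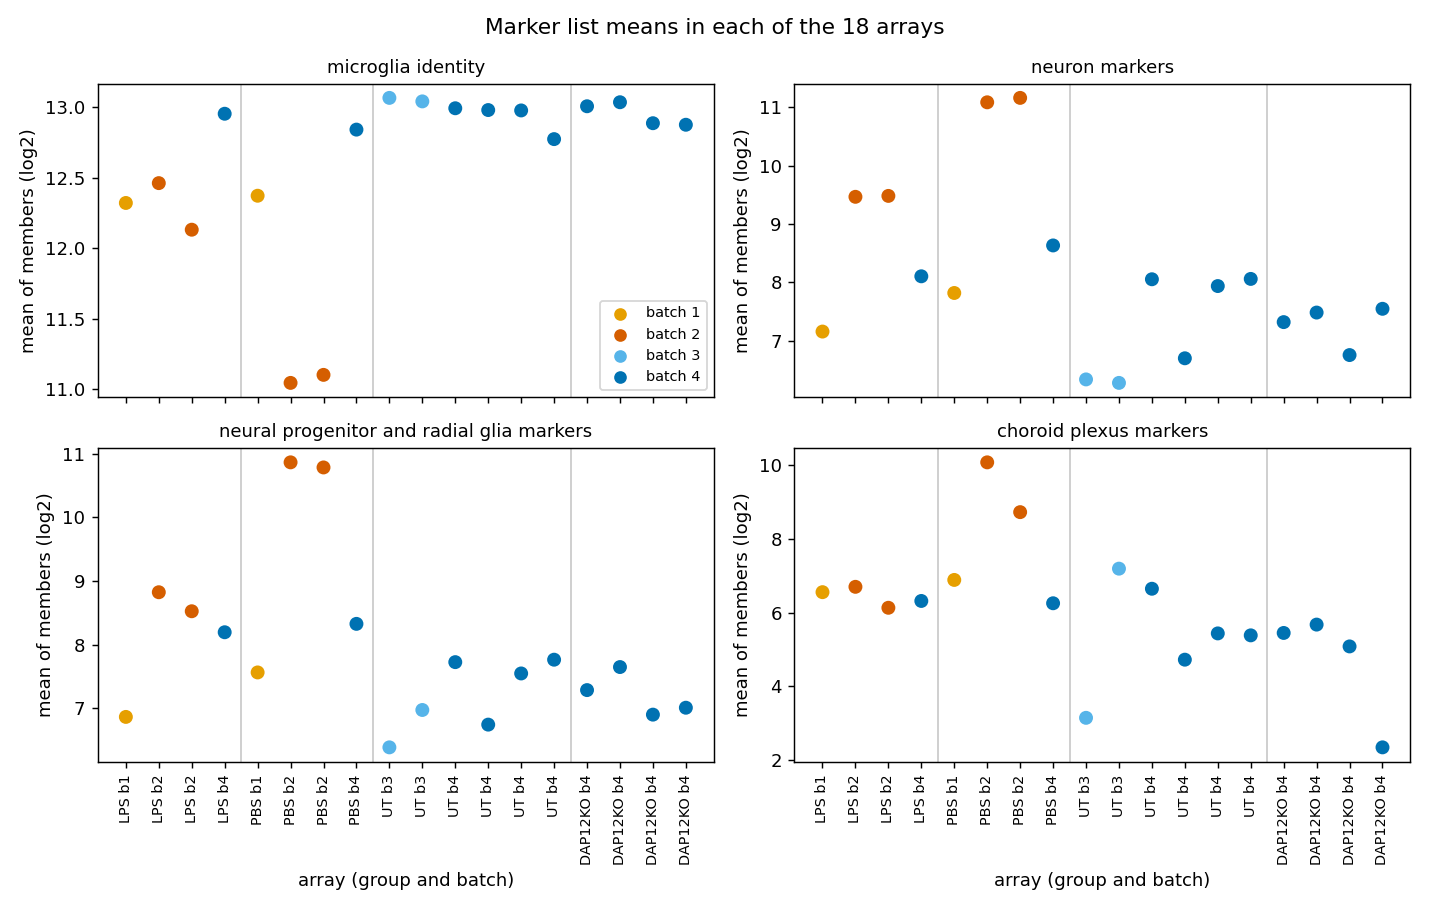
Mean log2 value of the microglia identity, neuron, neural progenitor and radial glia, and choroid plexus markers (vertical axis) in each of the 18 arrays (horizontal axis), 1 point per array, coloured by batch. The 2 PBS arrays of batch 2 hold the highest neuron marker means (11.08 and 11.16) and the lowest microglia identity means (11.04 and 11.10).

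The comparison of LPS with PBS asks how inflammation of the mother changes gene expression in the microglia of the embryo. Csf3r, the receptor for granulocyte colony-stimulating factor, rose by 2.25 ± 0.39 log2 (SE, n = 4 arrays per group, adjusted p = 0.0444), from 6.77 ± 2.28 (SD) with PBS to 9.02 ± 1.26 with LPS. Sema3a, a secreted semaphorin that repels growing axons, fell by 4.51 ± 0.68 (adjusted p = 0.0344), from 7.001 ± 2.76 to 2.49 ± 0.34. Ptx3, a secreted pattern recognition molecule of innate immunity, fell by 3.52 ± 0.57 (adjusted p = 0.0444), from 6.10 ± 2.60 to 2.58 ± 0.65. Chrna7, a subunit of the nicotinic acetylcholine receptor, fell by 2.80 ± 0.43 (adjusted p = 0.0344), from 5.61 ± 1.23 to 2.81 ± 0.83. Csf3r was higher in 4 of 4 LPS arrays than the PBS mean of their batch, and Sema3a, Ptx3 and Chrna7 were lower in 4 of 4. For these 3 genes 3 of 4 LPS arrays were near the floor, and with such values set to the threshold of 2.49 the differences were −4.38, −3.34 and −2.73.

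The other 7 genes that fell include the protocadherins Pcdh19 (by 3.29 ± 0.57) and Pcdhb9 (by 3.28 ± 0.58), which mediate adhesion between neurons. They also include Mapk8ip1, a scaffold of JNK signalling (fell by 3.17 ± 0.56), Sult4a1, a brain sulfotransferase (fell by 3.10 ± 0.54), and Pxylp1, a xylose phosphatase of proteoglycan synthesis (fell by 3.56 ± 0.60). Ccdc120 fell by 3.04 ± 0.41 with the lowest adjusted p, 0.0208, and the other adjusted p values of these 7 genes reached at most 0.0453. Pcsk5, a proprotein convertase, was near the floor in 4 of 4 LPS arrays, at least 5.23-fold lower than with PBS. In batch 1 both of its arrays were near the floor, and the other 6 genes were lower in 4 of 4 LPS arrays. Of the 10 genes that fell, 9 had 2 to 4 LPS arrays near the floor, Pxylp1 being the exception with 0. With such values set to the threshold the differences were −3.12 for Pcdh19 (3 LPS arrays and 1 PBS array near the floor), −3.13 for Pcdhb9, −3.12 for Mapk8ip1, −2.94 for Sult4a1 and −2.89 for Ccdc120. By the same rule DAP12KO minus UT of batch 4 was 0 for Ptx3, Pcdh19, Pcdhb9 and Pcsk5. Untreated microglia of batch 4 thus stood at the threshold for these genes, and the PBS mean lay above them. For Sema3a, Chrna7 and Ccdc120 that difference was −0.06, −0.08 and −0.08.

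In all, 11 of 11630 genes passed in limma, 1 higher and 10 lower with LPS. At an unadjusted p under 0.05 there were 1447, of which 403 were higher and 1044 lower, against 581.5 expected by chance. The difference within batches 1, 2 and 4 was 2.88, 2.70 and 0.70 for Csf3r, −7.51, −4.80 and −0.92 for Sema3a, −1.16, −5.35 and −2.20 for Ptx3, and −1.78, −3.14 and −3.14 for Chrna7. The 2 PBS arrays of batch 2 carried the neural markers at the highest level, and Xist, the RNA that silences an X chromosome in female cells, was at 2.21 in both, against 12.01 and 13.62 in the other PBS arrays and 12.85 to 13.09 in the 4 LPS arrays (named after its values were seen). Without the 2 PBS arrays of batch 2, 9 genes passed, 8 higher and 1 lower (AI593442, Celf6, Col23a1, Gcap8, Loxl1, Mob3b, Pqlc3 and Thnsl1 higher, Rnpc3 lower), and without all of batch 2 there were 5, all higher (Celf6, Col23a1, Gcap8, Loxl1 and Mob3b). Both of these fits, and the names from them, were chosen after seeing the data, and 0 of the 11 genes were among the 9 or the 5. There Sema3a stood at −4.22, Chrna7 at −2.46 and Csf3r at 1.79, while Ptx3 (−1.68), Ccdc120 (−1.99) and Pcsk5 (−1.72, with its LPS values near the floor) moved by over 1.5 times. Without the batch term, or without any 1 of the 4 arrays of batch 2 (LPS replicates 1 and 2, PBS replicates 1 and 2), 0 genes passed. There were also 0 with only these 2 groups, with the replicate number as a block, with a filter at the 60th percentile, with the neuron marker mean as a covariate, and by a plain test per gene (343 at an unadjusted p under 0.05). The block takes up the likeness of same-numbered LPS and PBS arrays in batch 2 (Pearson r = 0.53), which the main fit leaves out. Without the LPS array of batch 4 there were 119, without the PBS array of batch 4 120, without the LPS array of batch 1 79, and without the PBS array of batch 1 77. With array weights there were 826.

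**Figure D2:**
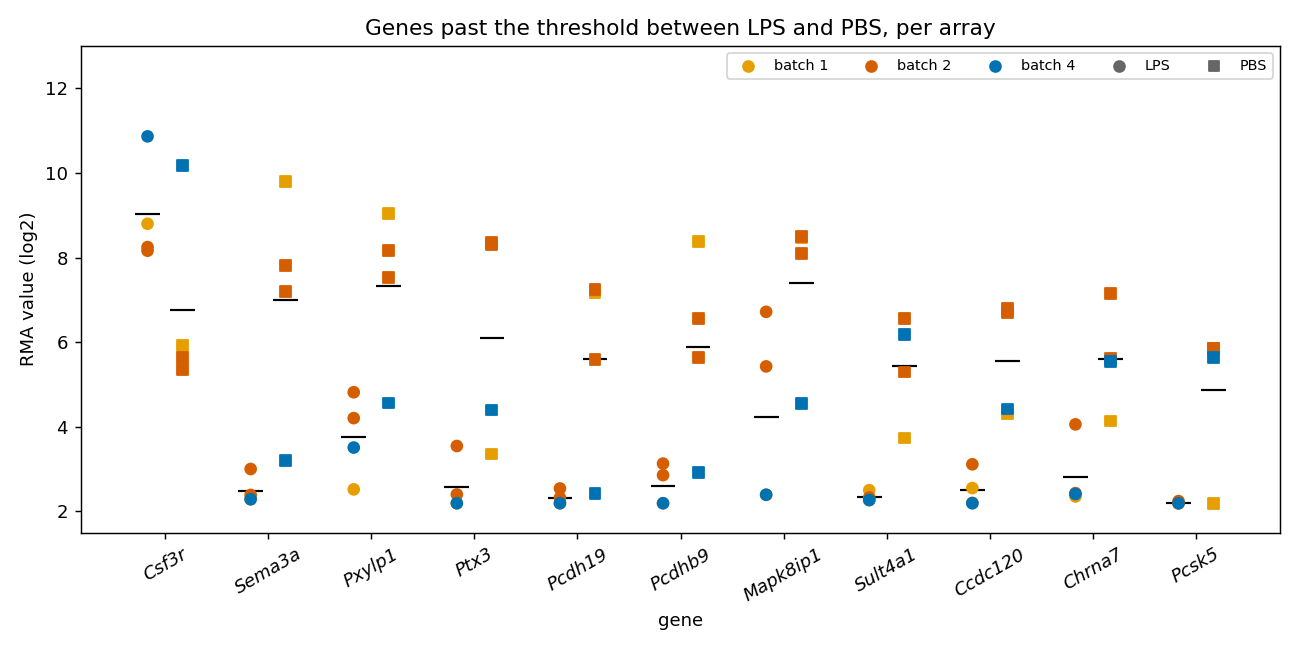
Log2 expression (vertical axis) of the 11 genes that passed (horizontal axis), 1 circle per LPS array and 1 square per PBS array (4 each), coloured by batch, with a line at each group mean. Csf3r rose by 2.25 and the other 10 fell, of which Sema3a fell by 4.51, and Pcsk5 was near the floor in all 4 LPS arrays.

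Microglia identity genes stood higher with LPS. All 28 measured members were above PBS, by a mean of 0.63, with 0 past the threshold over all genes and 6 adjusted over the list alone. The list was called by camera (adjusted p = 2.94e-10), with an adjusted p = 0.308 with an estimated correlation. Itgam, an integrin of complement receptor 3, was 2.25 ± 0.43 higher (adjusted p = 0.0648, 4 of 4 arrays), P2ry12, a purine receptor of microglia, 0.64 ± 0.18 (adjusted p = 0.174), Olfml3 0.62 ± 0.17 and Siglech 0.86 ± 0.27. Cx3cr1, the fractalkine receptor, differed by 0.74 ± 0.24 (adjusted p = 0.236), Csf1r by 0.21 ± 0.10 (0.414) and Aif1 by 0.24 ± 0.17 (0.587), the last being 0.09 without PBS replicate 1 and 0.10 without LPS replicate 2 of batch 2, and 0.37 without either array of batch 4. The list mean was −0.05, 1.23 and 0.11 in batches 1, 2 and 4, and the neuron markers in the same batches were −0.66, −1.65 and −0.53. Without the 2 PBS arrays of batch 2 the list mean was 0.03 (adjusted p = 0.88). Against the UT arrays, which are of other batches, the list stood at −0.68 in the LPS arrays of batch 2 and −1.90 in its PBS arrays.

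Several lists of immune receptor and clearance genes went the same way. Among 20 measured genes of DAP12 and its partners, 16 were higher (mean 0.42, camera adjusted p = 0.000146), with an adjusted p = 0.332 with an estimated correlation. Syk, the kinase that DAP12 recruits, stood 1.45 ± 0.53 higher and Plcg2 0.89 ± 0.34, against 1.04 ± 0.39 for Trem2 (adjusted p = 0.296) and 0.16 ± 0.13 for Tyrobp (adjusted p = 0.646). TREM2-dependent and lipid-lysosome genes had 18 of 24 members higher (mean 0.37, adjusted p = 0.00174), among them Ctsd (0.31 ± 0.16) and Cd68 (0.40 ± 0.22). Phagocytosis and lysosome genes had 24 of 26 higher (mean 0.34, adjusted p = 0.000114), led by the protease Lgmn (0.83 ± 0.23), with Hexa at 0.36 ± 0.14, Ctss at 0.30 ± 0.12 and Npc2 at 0.30 ± 0.12. With an estimated correlation both had an adjusted p = 0.332. Complement genes had 10 of 11 higher (mean 0.62, adjusted p = 0.00345; 0.308 with an estimated correlation), with C1qc at 0.40 ± 0.18, C2 at 2.68 ± 1.09 (7.23, 2.2 and −0.92 in batches 1, 2 and 4) and the inhibitor Serping1 at −1.21 ± 0.49. Antigen presentation genes had 12 of 13 higher (mean 0.42, adjusted p = 0.00718), with the class I genes H2-K1 at 0.94 ± 0.29 and H2-D1 at 1.12 ± 0.45, B2m at 0.24 ± 0.11 and Cd86 at 0.46 ± 0.34 (−0.95 in batch 4). Chemokine receptors and adhesion genes had 12 of 19 higher (mean 0.20, adjusted p = 0.00836), with Itgb2 at 0.84 ± 0.34 and the adhesion molecule Vcam1 at −2.33 ± 0.79. With an estimated correlation the last 2 lists had an adjusted p = 0.332. Over all genes 0 members of these lists passed, and adjusted over the list alone Itgam passed in the complement and the chemokine receptor lists and 0 members in the others. Single arrays moved several of these values, none of them past the threshold, by over 1.5 times: without PBS replicate 1 of batch 2 Cd68 was 0.15, C1qc 0.12, Serping1 −0.78, Hexa 0.23, Trem2 0.64 and Ctsd 0.20. Without LPS replicate 1 of batch 2 Ctsd was 0.14, Trem2 0.64, B2m 0.16 and Tyrobp 0.08, and without PBS replicate 2 Ctss was 0.14 and Tyrobp 0.09. Without either array of batch 1 C2 was 1.16, H2-D1 0.74, Npc2 0.45 and Tyrobp 0.28, and without either array of batch 4 Itgb2 was 1.37. With each array left out in turn Cd86 ran from 0.20 to 0.93.

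In these 6 lists the difference was largest in batch 2, where the PBS arrays held the most neural RNA. The DAP12 list was −0.38, 1.14 and −0.20 in batches 1, 2 and 4, the TREM2-dependent list −0.20, 0.82 and 0.02, and the phagocytosis list −0.20, 0.92 and −0.28. Antigen presentation genes were −0.13, 1.07 and −0.34, the chemokine receptor list −0.39, 0.70 and −0.22, and complement genes 0.66, 0.80 and 0.24. Against the UT arrays, which are of other batches, the LPS arrays of batch 2 were not higher. They stood at −0.53 (DAP12), −0.91 (TREM2-dependent), −0.31 (phagocytosis), −0.47 (antigen presentation), −0.69 (chemokine receptors) and −0.02 (complement). Without batch 2, or without its 2 PBS arrays, the list means were −0.29 (DAP12), −0.09 (TREM2-dependent), −0.24 (phagocytosis), −0.23 (antigen presentation), −0.30 (chemokine receptors) and 0.45 (complement), with 0 of the 6 called. Single arrays also ended calls: without LPS replicate 1 of batch 2 the TREM2-dependent list was 0.16, antigen presentation 0.27 and chemokine receptors 0.02. Without PBS replicates 1 and 2 of batch 2 in turn, antigen presentation was 0.30 and 0.27 and the chemokine receptors 0.17 and 0.02, and without LPS replicate 2 of batch 2 the latter were 0.17, all past the threshold no longer. Means that stayed called moved by over 1.5 times for the DAP12 list without LPS or PBS replicate 1 of batch 2 (0.25 and 0.27), for the TREM2-dependent list without PBS replicate 2 of batch 2 (0.20), and for the phagocytosis list without LPS replicate 1 or PBS replicate 2 of batch 2 (0.16 and 0.15). They rose without the LPS or the PBS array of batch 1, to 0.69 (DAP12), 0.56 (TREM2-dependent), 0.52 (phagocytosis) and 0.39 (chemokine receptors), and without either array of batch 4, to 0.67 (antigen presentation), 0.55 (phagocytosis) and 0.33 (chemokine receptors).

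Inflammatory genes were mostly higher with LPS, with Ptx3 as the member that passed and fell. Of 26 cytokines and NF-κB targets 22 were higher (mean 0.57, camera adjusted p = 0.000292; 0.332 with an estimated correlation), and 1 passed both over all genes and adjusted over the list alone. The chemokines Ccl4 and Ccl5 differed by 1.51 ± 0.52 and 2.84 ± 1.06, and the cytokine Il1a by 1.18 ± 0.46, each higher in 4 of 4 arrays than the PBS mean of their batch. Tnf (1.44 ± 0.89, adjusted p = 0.526) was 4.46, 0.03 and 1.25 higher in batches 1, 2 and 4, and Il1b differed by 1.47 ± 1.51 (adjusted p = 0.746). Type I interferon response genes had 19 of 21 higher (mean 0.86, adjusted p = 0.000457; 0.419 with an estimated correlation), with Oasl2 at 2.65 ± 0.83, Usp18 at 2.69 ± 1.25 (3 of 4 PBS arrays near the floor), Ifit3 at 1.53 ± 0.84, Oas1a at 1.19 ± 0.64 (−1.30 in batch 4) and 0 members past the threshold by either adjustment. Immediate early genes, which respond within minutes to signals and also to tissue handling, had 20 of 22 higher (mean 0.44, adjusted p = 0.000185; 0.320 with an estimated correlation), with 0 past the threshold over all genes. Adjusted over the list alone 1 passed, Klf2 (2.63 ± 0.55), and Egr1, Rhob and Btg2 were 0.31 ± 0.13, 0.53 ± 0.18 and 0.75 ± 0.36 (Btg2 −0.12 in batch 4). Of the values not past the threshold, those that a single array moved by over 1.5 times were Ccl5 (1.39), Tnf (0.44), Usp18 (1.52) and Oas1a (0.78) without either array of batch 1, Oas1a (2.02) without either array of batch 4, Ccl4 without PBS replicate 2 (0.91) or LPS replicate 1 (0.93) of batch 2, and Btg2 without PBS replicate 1 of batch 2 (0.46).

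Within batches 1, 2 and 4 the inflammatory list was 1.30, 0.56 and −0.16, the interferon list 0.52, 1.47 and −0.04, and the immediate early list 0.90, 0.68 and −0.48, while neuron markers were lower in each of these batches (−0.66, −1.65 and −0.53). Without batch 2, or without its 2 PBS arrays, these 3 lists were at 0.57, 0.24 and 0.21, and 0 of them was called. Against the UT arrays, which are of other batches, the LPS arrays of batch 2 stood at −0.45, 0.007 and −0.09 in these lists. Without either array of batch 1 the inflammatory list was 0.32 and the immediate early list 0.29, and without either array of batch 4 the latter was 0.75, all still called.

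Neural genes stood lower with LPS. Neuron markers had 22 of 23 members lower (mean −1.12, camera adjusted p = 0.000114), with Rbfox3 at −2.38 ± 0.85, the glutamate transporter Slc17a6 at −2.52 ± 0.97, Nefm at −1.26 ± 0.36 and Rtn1 at −1.18 ± 0.45. Neural progenitor and radial glia markers had 16 of 17 lower (mean −1.28, adjusted p = 9.21e-05), with Tnc at −2.95 ± 0.73, Slc1a3 at −2.004 ± 0.66, Emx2 at −1.68 ± 0.60 and Fabp7 at −0.75 ± 0.23. Axon guidance and neurite outgrowth genes had 48 of 54 lower (mean −1.01, adjusted p = 1.79e-06), with Sema3a past the threshold and the growth factors Mdk (−2.38 ± 0.51, adjusted p = 0.0998) and Ptn (−2.14 ± 0.50) and the receptor Ntrk2 (−2.20 ± 0.50) next. Synapse genes had 22 of 25 lower (mean −1.10, adjusted p = 0.000372), with Cplx2 at −2.27 ± 0.49 (adjusted p = 0.101), Nlgn3 at −2.23 ± 0.62, Pclo at −2.01 ± 0.53 (3 of 4 LPS arrays near the floor) and the glutamate receptor Gria4 at −1.46 ± 0.48 (2 of 4; −0.87 without PBS replicate 1 of batch 2). With an estimated correlation each of these 4 lists had an adjusted p = 0.308, and by fry 0.036. Over all genes 0, 0, 1 and 0 members passed, in the order given, and adjusted over the list alone 0, 3, 6 and 4.

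These differences were largest in batch 2, where the 2 PBS arrays had neuron means of 11.08 and 11.16 and the 2 LPS arrays 9.46 and 9.48. In batches 1, 2 and 4 the means were −0.66, −1.65 and −0.53 (neuron), −0.70, −2.15 and −0.13 (progenitor), −0.32, −1.66 and −0.41 (axon guidance), and −0.18, −1.81 and −0.59 (synapse). Without batch 2, or without its 2 PBS arrays, they were −0.60, −0.42, −0.37 and −0.38, and 0 of the 4 lists was called.

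**Figure D3:**
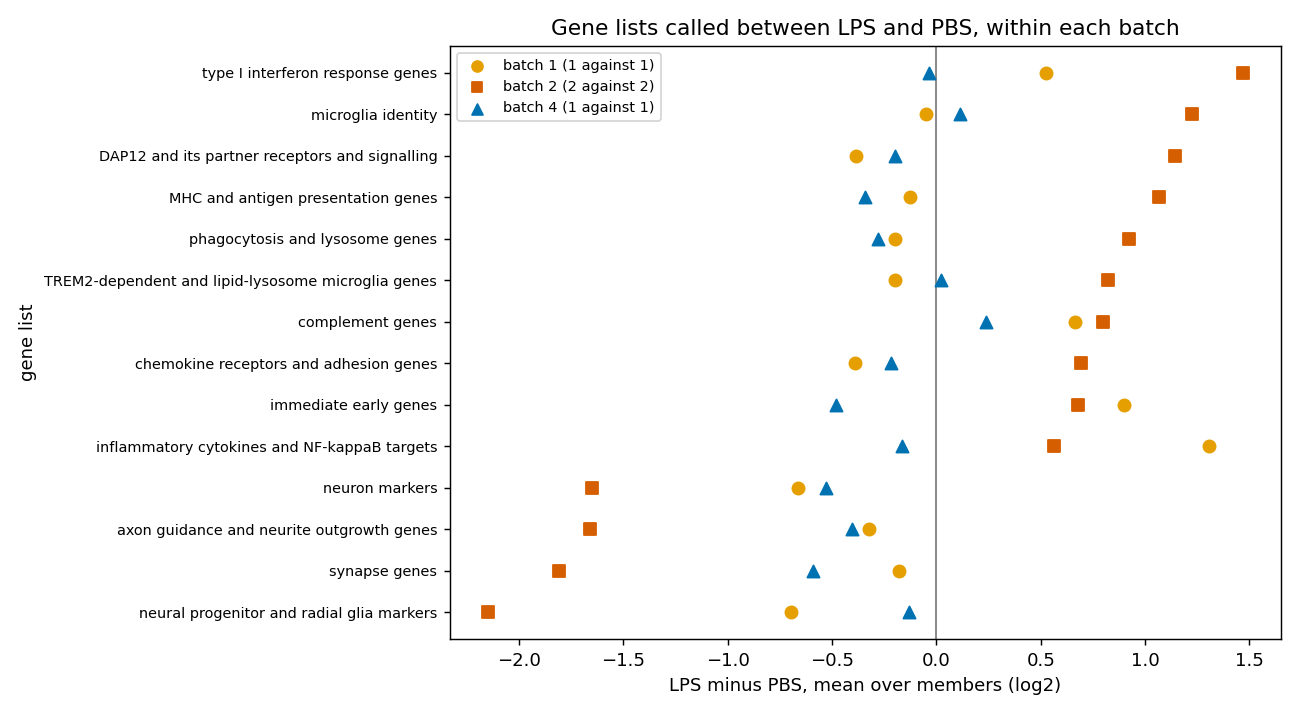
Mean log2 difference LPS minus PBS (horizontal axis) of the 14 called lists (vertical axis), 1 point per list for each of batches 1, 2 and 4. In batch 2 the microglia identity list lies at 1.23 and the progenitor list at −2.15, against −0.05 and −0.70 in batch 1 and 0.11 and −0.13 in batch 4.

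With the neuron marker mean as a covariate, a fit chosen after seeing the data, 1 of the 14 lists stayed called, type I interferon response genes. The neuron markers lost their call there by construction. The axon guidance and synapse lists share members with them, so that the loss of these calls was in part fixed beforehand. Antigen presentation genes were also no longer called with no filter on dim probe sets (0.28). Of the 40 lists, 14 were called by camera (10 higher, 4 lower), 0 with an estimated correlation (lowest adjusted p = 0.308) and 6 by fry. The 6 were the neuron, progenitor, axon guidance, synapse and complement lists and mural cell markers (mean −1.14, camera adjusted p = 0.0779). The 26 lists not called had adjusted p from 0.0779 to 0.965. They include TLR4 pathway components, the receptor chain of LPS (mean 0.24, adjusted p = 0.155), G1/S and G2/M cell cycle genes (0.03 and 0.11, adjusted p = 0.405 and 0.175) and oxidative phosphorylation genes (−0.20, adjusted p = 0.353). Among lists not called, mean, median and camera direction differed in sign for border macrophage, monocyte, sex-linked, heat shock, glycolysis, ribosomal protein and glucocorticoid response genes. The median over all genes was −0.12.

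The comparison of DAP12KO with UT asks what loss of the adaptor changes in otherwise untreated embryonic microglia. Tyrobp itself, on chromosome 7, stood at 13.9 ± 0.219 (SD, n = 4) in DAP12KO and 14.5 ± 0.0616 in the 4 UT arrays of batch 4, a difference of −0.60 ± 0.13 (SE) that did not pass over all genes (adjusted p = 0.301). It was lower in 4 of 4 arrays than the UT mean of the batch, and it was the 1 member of the DAP12 list to pass adjusted over the list alone. The labels do not say which part of the gene is altered, so that this probe set may check nothing about the genotype. Microglia identity was level: the 28 genes differed by a mean of 0.02 (camera adjusted p = 0.905), at 12.95 ± 0.08 (SD) in DAP12KO and 12.93 ± 0.11 in UT of batch 4. Cx3cr1 differed by −0.07 ± 0.24, Csf1r by 0.02 ± 0.10, Itgam by −0.003 ± 0.43 and P2ry12 by 0.06 ± 0.18 (each adjusted p = 1), Trem2 by 0.47 ± 0.39 (0.926) and Aif1 by 0.36 ± 0.17 (0.902).

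In limma 0 of 11630 genes passed (smallest adjusted p = 0.301), 637 had an unadjusted p under 0.05 (346 higher, 291 lower; 581.5 expected by chance), and a plain test per gene gave 0. The genes with the lowest p, which did not pass (adjusted p from 0.301 to 0.46), included Aptx, a DNA repair enzyme (3.43 ± 0.68), Acp5, the tartrate-resistant acid phosphatase (3.49 ± 0.78), Med29 (2.40 ± 0.51) and Bend3 (2.43 ± 0.56). Troap, a protein of the mitotic spindle, was near the floor in all 4 UT arrays of batch 4 and at least 8.24-fold higher in DAP12KO. Lower were Tlcd3b (−4.08 ± 0.85), the methyltransferase Setd7 (−3.48 ± 0.74), Lrba (−3.44 ± 0.73) and Nif3l1 (−2.89 ± 0.61). Each of these 9 lay on 1 side of the UT mean of the batch in 4 of 4 arrays. Tnf differed by 2.69 ± 0.89 (adjusted p = 0.788) and Il1b by 2.71 ± 1.51 (adjusted p = 0.908), which was 4.57 without DAP12KO replicate 1. The count became 6 without DAP12KO replicate 5 (Aptx, Khdc1b, Med29, Slc30a10, Tirap and Troap), 4 without UT replicate 1 of batch 4 (AI504432, Acp5, C920021L13Rik and Zscan2), 2 without DAP12KO replicate 4 (Niban3 and Stx1a), 2 without UT replicate 6 of batch 4 (Arap2 and Elmo3), and 0 without each of the others. These names were chosen after their values were seen.

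Type I interferon response genes stood higher in DAP12KO, with 18 of 21 members up (mean 1.06, camera adjusted p = 0.0025; 0.773 with an estimated correlation). Ifit1 differed by 2.85 ± 1.34, Rsad2 by 2.58 ± 1.49, Mx1 by 2.29 ± 1.07 and the transcription factor Irf7, near the floor in 2 DAP12KO arrays and 3 of the 4 UT arrays, by 1.55 ± 0.78. The list mean was 10.27 in DAP12KO replicate 2, 8.12 in replicate 4 and 6.75 and 7.06 in replicates 1 and 5, against 8.68 in UT replicate 6 and 6.10 to 6.76 in the other UT arrays of batch 4. Without DAP12KO replicate 2 it differed by 0.32 (adjusted p = 0.551), and without UT replicate 6 by 1.62. Without DAP12KO replicate 2 Ifit1 was 1.85, Rsad2 1.26, Mx1 1.18 and Irf7 0.70. G2/M cell cycle genes had 20 of 23 higher (mean 0.41, adjusted p = 0.00481; 0.451 with an estimated correlation). Nusap1 was at 0.97 ± 0.41, the kinase Ttk at 1.58 ± 0.72, Top2a at 0.75 ± 0.38 and Mki67 at 0.29 ± 0.14, each higher in 4 of 4 arrays than the UT mean of the batch. The 2 UT arrays of batch 3 had G2/M means of 10.40 and 10.55, against 9.80 to 10.57 in DAP12KO and 9.70 to 10.01 in UT of batch 4. The call ended without DAP12KO replicate 2 (0.31, adjusted p = 0.0736) and without the batch term.

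Border macrophage markers stood lower in DAP12KO. Macrophages of the meninges, perivascular spaces and choroid plexus carry them, and 12 of 15 members were down (mean −0.65, camera adjusted p = 0.0154; 0.773 with an estimated correlation). Lyve1 differed by −2.72 ± 0.82, the coagulation factor F13a1 by −1.84 ± 0.76, Pf4 by −1.22 ± 0.56 and the mannose receptor Mrc1 by −0.58 ± 0.28. The call ended without DAP12KO replicate 1 (−0.52) or 2 (−0.78), or UT replicate 3 (−0.45) or 6 (−0.41) of batch 4, and with the neuron marker mean as a covariate (−0.57), and F13a1 was −1.11 without DAP12KO replicate 4. Neural lists were lower too. Neuron markers had 18 of 23 members down (mean −0.41, adjusted p = 0.022; 0.773 with an estimated correlation), with Tbr1 at −1.82 ± 0.73, Elavl3 at −2.70 ± 1.18, Map2 at −1.12 ± 0.57 and Ina, against the rest, at 2.12 ± 1.01. Interneuron markers had 8 of 11 down (mean −0.49, adjusted p = 0.0154; 0.451 with an estimated correlation), with Sst at −0.97 ± 0.48, Dlx2 at −1.04 ± 0.58, Reln at −0.74 ± 0.43 and Gad1 near the floor in all 4 DAP12KO arrays. Axon guidance genes had 41 of 54 down (mean −0.46, adjusted p = 0.000484; 0.557 with an estimated correlation), with Plxna2 at −3.42 ± 0.98, Cntn2 at −1.87 ± 0.74, Kif5c at −1.39 ± 0.52 and Ephb1 at −1.30 ± 0.55. Without DAP12KO replicate 4, where Elavl3 was near the floor, Elavl3 was −1.06, Map2 −0.52 and Reln −0.33. Without UT replicate 2 of batch 4 Ina was 0.97, and without UT replicate 3 Sst was −0.57.

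Neuron marker means by array were 6.75 to 7.54 in DAP12KO, 6.70 to 8.06 in UT of batch 4, and 6.27 and 6.33 in UT of batch 3. Without the batch term the neuron list stood at 0.05 and the interneuron and axon guidance lists were no longer called. The neuron call ended without DAP12KO replicate 2 (−0.48) or 4 (−0.24) and without UT replicate 1 (−0.29), 3 (−0.33) or 6 (−0.29) of batch 4, and without UT replicate 2 the mean was −0.74. The interneuron call ended without DAP12KO replicate 2 (−0.50) or 4 (−0.42), and the axon guidance call without DAP12KO replicate 2 (−0.38). The neuron call also ended with only the 2 groups (−0.41, adjusted p = 0.0586), and the interneuron call with the Gapdh covariate (−0.43) and with values under log2 4 set to 4 (−0.29). With the neuron marker mean as a covariate the interneuron (−0.38) and axon guidance (−0.24) calls ended, as did that of the neuron markers themselves, by construction. Over all genes and adjusted over the list alone, 0 members of the 6 called lists passed. The other 34 lists had adjusted p from 0.0716 to 0.962, and 0 lists were called with an estimated correlation or by fry. Among the 34, TREM2-dependent genes differed by a mean of −0.01 (adjusted p = 0.801), inflammatory genes by 0.50 (0.0716) and synapse genes by −0.40 (0.0716). Mean, median and camera direction differed in sign for the monocyte, DAP12, phagocytosis, trophic factor, glycolysis and cholesterol lists.

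**Figure D4:**
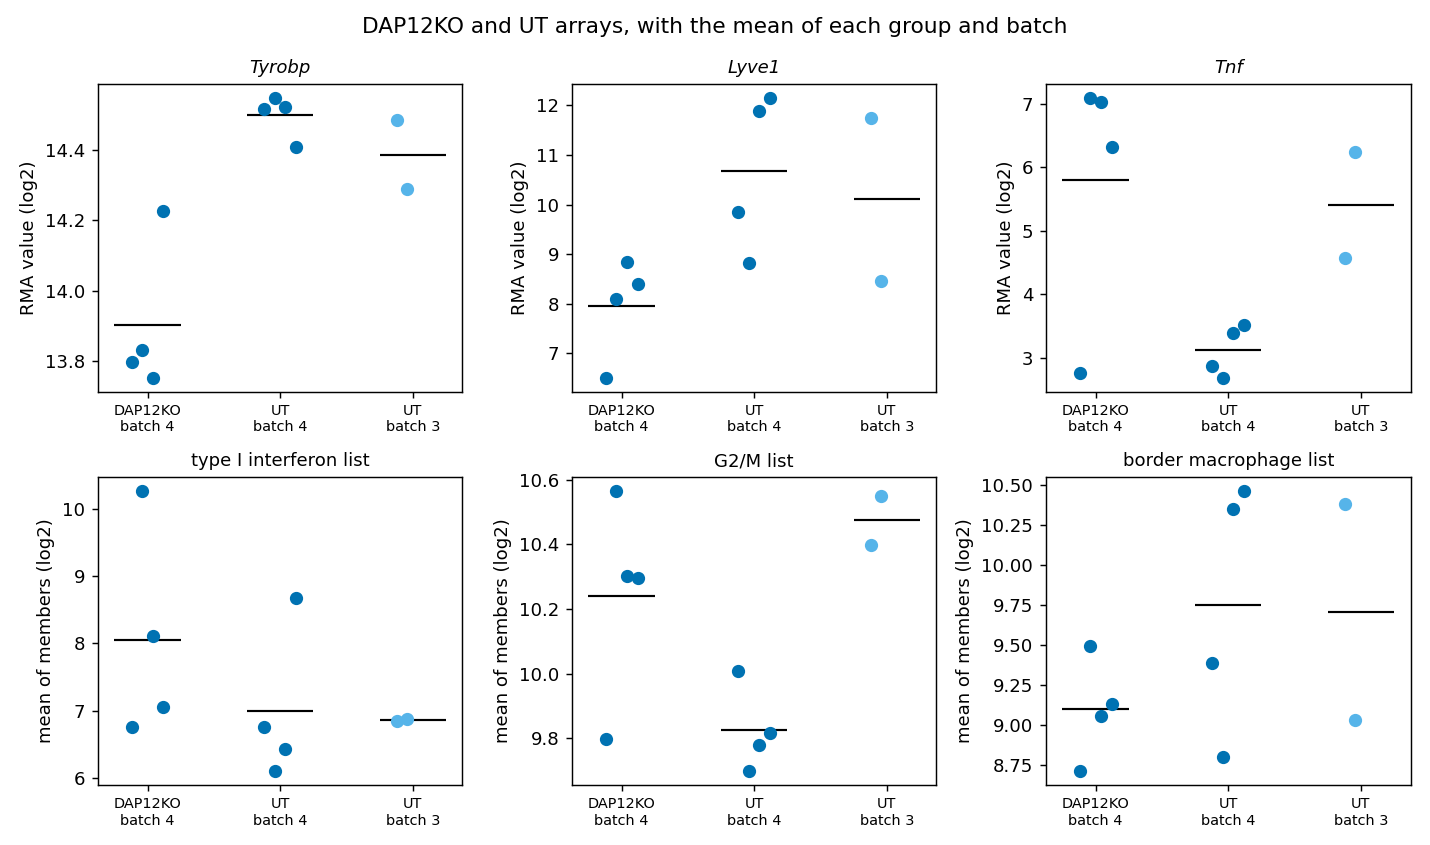
Log2 value (vertical axis) of Tyrobp, Lyve1 and Tnf, and list means of type I interferon response, G2/M and border macrophage genes, in the DAP12KO arrays of batch 4, the UT arrays of batch 4 and the UT arrays of batch 3 (horizontal axis), 1 point per array. Tyrobp lies at 13.8 to 14.2 in DAP12KO and 14.4 to 14.5 in UT of batch 4, and the interferon mean of 10.27 in DAP12KO comes from a single array.

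The difference between the responses asks whether LPS and loss of DAP12 act differently on a gene. In limma 0 of 11630 genes passed (smallest adjusted p = 0.449; median over genes −0.17, and −0.04 with quantile normalization on top), with 943 at an unadjusted p under 0.05 (270 higher, 673 lower). The genes with the lowest p did not pass (adjusted p = 0.449 each). Among them the LPS response exceeded the DAP12KO response for Tyrobp by 0.76 ± 0.18, Csf3r by 2.38 ± 0.56, Cyb561a3 by 2.05 ± 0.45 and Frrs1 by 2.27 ± 0.56. The class II gene H2-Ob was also among them, near the floor in 4 of 4 DAP12KO and 3 of 4 PBS arrays and at least 4.53-fold lower in DAP12KO than in UT of batch 4. It lay below for Snrnp25 (−3.18 ± 0.57), Ccdc120 (−2.89 ± 0.58), Sult4a1 (−3.60 ± 0.76), Aptx (−4.53 ± 0.95) and Sema3a (−4.40 ± 0.95). For Ccdc120, Sult4a1 and Sema3a, 3 or 4 of the 4 arrays were near the floor in DAP12KO and in UT of batch 4, so that their DAP12KO response was hardly measured. With batch 2 and only the DAP12KO and UT arrays of batch 4, and no batch term, 271 genes passed (29 higher, 242 lower). The LPS response in that fit rests on batch 2 alone. With array weights 11 passed, without the LPS or the PBS array of batch 4 18 each, and without the LPS or the PBS array of batch 1 9 each. Without DAP12KO replicate 4 there was 1 (Niban3, named after its value was seen).

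By camera 8 lists differed between the responses, 7 of them with the LPS response above the DAP12KO response: microglia identity (mean 0.61, adjusted p = 2.01e-06), phagocytosis and lysosome genes (0.50, 0.00089), DAP12 and its partners (0.53, 0.00206), TREM2-dependent genes (0.38, 0.0118), complement genes (0.70, 0.0219), immediate early genes (0.32, 0.0219) and border macrophage markers (0.51, 0.043). The border macrophage mean was −0.14 with LPS and −0.65 in DAP12KO. For neural progenitor and radial glia markers the LPS response lay below (−1.05, 0.034). With an estimated correlation the adjusted p of the 8 lists lay between 0.702 and 0.79, and 0 were called by that test or by fry. Without the 2 PBS arrays of batch 2 the means were 0.01 for microglia identity, −0.08 for phagocytosis, −0.19 for DAP12, −0.08 for TREM2-dependent genes, 0.53 for complement, 0.09 for immediate early genes, −0.33 for border macrophages and −0.18 for progenitors, with 0 called. Without LPS replicate 1 of batch 2 alone only microglia identity stayed called, with 0.32 for phagocytosis, 0.35 for DAP12, 0.17 for TREM2-dependent genes, 0.65 for complement, 0.25 for immediate early genes, 0.27 for border macrophages and −0.93 for progenitors.

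The weaker of these calls also ended without other single arrays, written here with R for replicate. For border macrophage markers these were DAP12KO R1 (0.38) and R4 (0.50), UT R3 (0.31) and R6 (0.27) of batch 4, and LPS R2 (0.41), PBS R1 (0.39) and PBS R2 (0.29) of batch 2. For progenitor markers they were DAP12KO R1 (−1.02) and R2 (−0.90), UT R2 of batch 4 (−0.82), and LPS R2 (−0.81), PBS R1 (−0.86) and PBS R2 (−0.89) of batch 2. For complement genes they were DAP12KO R4 (0.61) and LPS R2 (0.69) and PBS R1 (0.67) of batch 2, and for TREM2-dependent genes PBS R2 of batch 2 (0.21). For immediate early genes they were DAP12KO R1 (0.21), UT R3 of batch 4 (0.24), LPS R2 (0.30) and PBS R1 (0.27) of batch 2, and the LPS or the PBS array of batch 1 (0.17 each). Means that stayed called moved by over 1.5 times without the LPS or the PBS array of batch 4 (border macrophages 0.86, immediate early genes 0.63), without the LPS or the PBS array of batch 1 (DAP12 0.80), without UT R2 of batch 4 (border macrophages 0.83) and without PBS R2 of batch 2 (phagocytosis 0.32). Among other fits, the border macrophage call ended without the batch term (0.50) and with quantile normalization (0.64) or median centring (0.55) on top, the complement call without the batch term (0.66), and every call but that of microglia identity with the neuron marker mean as a covariate.

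Over genes the responses correlated with Pearson r = 0.0897 and Spearman rho = 0.074 (11630 genes, which are not independent replicates). Genes at an unadjusted p under 0.05 in both comparisons numbered 8 higher in both (11.99 expected, Fisher's exact p = 0.295), 34 lower in both (26.1, 0.118), 6 higher with LPS and lower in DAP12KO (10.1, 0.253), and 15 lower with LPS and higher in DAP12KO (31.1, 0.00111). Fisher's exact test takes genes as independent, which they are not, so that its p values can be too small. The comparisons share no control arrays.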

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

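Chosen only after the result was seen were the count of marker lists, the fit without batch 2, the count of DAP12KO arrays above UT (with and without UT replicate 6), the regrouping within batches, the regrouping of the DAP12KO and UT arrays and of all arrays, and the use of the Gapdh covariate and of the fit without DAP12KO replicate 2, both fixed beforehand as settings, to weigh an explanation.

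Neural genes lower and microglia genes higher with LPS may come from RNA of other cell types in the 2 PBS arrays of batch 2, since in 8 of 9 neural, vascular and stromal marker lists these arrays held the 2 highest means, although the cells were sorted for GFP at the Cx3cr1 locus, which should remove such cells. RNA integrity stays open. With the Gapdh 3′ minus 5′ difference as a covariate the neuron markers stayed at −1.12, but this fit could hardly move them. The Gapdh difference was nearly balanced between the groups, at 0.96, 2.23, 2.96 and 2.73 in the LPS arrays and 0.98, 2.46, 3.33 and 2.01 in the PBS arrays. Within batch 2 it was higher in PBS than in LPS for the same replicate number (2.46 against 2.23, and 3.33 against 2.96), but the ranges overlapped. Whether maternal LPS treatment adds to it stays open: without batch 2 the neuron markers were at −0.60 (adjusted p = 0.908). The neuron means of these 2 PBS arrays (11.08 and 11.16) lay above those of the other 2 PBS arrays (7.82 and 8.63), a gap between arrays without LPS, while the gap to the LPS arrays of the same batch (9.46 and 9.48) stays open. The gap to the other PBS arrays is also one between batches. The LPS arrays of batch 2 too lay above the UT arrays, by 2.25 for neuron and 1.48 for progenitor markers. For oligodendrocyte lineage and endothelial markers they lay at −0.21 and −0.10. The sex of the pools, uneven in batch 2 by Xist (2.21 in both PBS arrays, 12.97 and 13.07 in the LPS arrays), also stays open, as it was not tested.

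Type I interferon response genes higher in DAP12KO could be the signal of a single pool, since without DAP12KO replicate 2 the difference was 0.32. Loss of DAP12 in every pool stays open: 1 of 4 DAP12KO arrays had a list mean above the highest UT array of batch 4, but 3 of 4 did without UT replicate 6, which itself lay far from the other UT arrays, and the difference without it was 1.62. A state of that litter and a technical effect on its sample were not told apart.

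For LPS and PBS, 35 groupings of the arrays into sets of 4 were possible and 34 could be fitted. Counting the real grouping, 8 of 34 gave as many genes as the real 11, with 442 as the highest other count, so that chance cannot be excluded. Of the 12 groupings that exchange arrays within batches only, which are too few for a share under 0.05, 2 gave as many, with 12 as the highest other count. The 2 groupings with 442 keep the batch 2 LPS arrays apart from the batch 2 PBS arrays and set the batch 1 and batch 4 arrays apart by batch. With the batch term they therefore carry the real LPS and PBS difference of batch 2. A grouping with 12 also keeps the real labels of batches 2 and 4. The groupings with 13 genes each split batch 2 by replicate number and set batches 1 and 4 apart by batch. They carry no LPS and PBS difference and still gave more genes than the real 11. The groupings with 17 and with the other 12 mix the labels within batch 2. The share of 8 in 34 thus counts groupings with and without the real difference and is no rate of chance, so that it neither excludes nor shows chance. Within batch 2 alone 40 genes passed for LPS against PBS, of which 1 (Pcsk5) is among the 11, and Xist is another of the 40 (named after its values were seen).

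For DAP12KO and UT, and for the difference of the responses, the real count was 0, which any grouping reaches (100 of 100 drawn from 210, and 98 of 98), so that these counts decide nothing. The highest other counts were 54, in a grouping that puts the UT arrays of batch 3 on 1 side, and 295.

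Of 294 values tested, 30 lay far from the other arrays of their group, a distance that chance gives in about 1 in 20 groups of normally distributed values. For this, gene values under the threshold of 2.49 were set to it, so that some of these arrays differ little from the others: Sult4a1 and Pcdh19 in LPS stood at 2.50 and 2.54 against 2.49. Where all arrays of a group but 1 were set to the threshold, the remaining array is always flagged and that rate does not hold. This was so for Sema3a, Ptx3, Pcdh19, Sult4a1, Chrna7 and Pclo in LPS, Usp18 in PBS and Irf7 in UT. In LPS these were Sema3a (3.002), Ccdc120 (3.11), Chrna7 (4.06) and Ccl4 (8.99) in replicate 2 of batch 2, and Ptx3 (3.55), Pcdh19, Pclo (3.38) and the actin 3′ minus 5′ difference (0.197) in replicate 1 of batch 2. In the LPS array of batch 1 they were Sult4a1, Mdk (7.36) and Klf2 (11.7), and in that of batch 4 Cx3cr1 (13.4). In the PBS array of batch 4 they were Csf3r (10.2), Mapk8ip1 (4.55), Usp18 (2.63), H2-K1 (11.7) and the complement list mean (9.77), in that of batch 1 Pcsk5 (at the 2.49 threshold) and Tnf (2.67), and in PBS replicate 1 of batch 2 Aif1 (13.52). In DAP12KO they were Il1b (2.58) and Setd7 (5.60) in replicate 1, Tlcd3b (5.24) in replicate 2, F13a1 (6.13) and Elavl3 (at the 2.49 threshold) in replicate 4, and Tyrobp (14.2) in replicate 5. In UT they were the microglia identity mean (12.8), the interferon list mean (8.68) and Irf7 (3.67) in replicate 6 of batch 4, and Troap (4.33) in replicate 4 of batch 3.

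Between the LPS response and the DAP12KO response 8 list means differed by camera: microglia identity by 0.61, border macrophage markers by 0.51, neural progenitor and radial glia markers by −1.05, DAP12 and its partners by 0.53, TREM2-dependent genes by 0.38, complement genes by 0.70, phagocytosis and lysosome genes by 0.50, and immediate early genes by 0.32. With an estimated correlation 0 of the 8 were called (adjusted p from 0.702 to 0.79). Without the 2 PBS arrays of batch 2, a fit chosen after seeing the data, 0 were called and 4 changed sign: border macrophage markers (−0.33), DAP12 (−0.19), TREM2-dependent genes (−0.08) and phagocytosis genes (−0.08).

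Among 4525 bright probe sets without a single gene name, tested on their own, 5 passed for LPS against PBS (3 higher, 2 lower; 598 at an unadjusted p under 0.05), 0 for DAP12KO (270) and 0 for the difference of the responses (397).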

How the results depend on the processing

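Signal over background limits these results, since 22.4% of tested genes had a value near the floor on 1 or more arrays, and batches 1 and 4 hold 1 LPS and 1 PBS array each. For gene lists, the random block, the fit without an intensity trend and the robust variance were not run, as they do not enter camera. For the difference of the responses, fewer groups and the plain test were not possible. Except where fewer arrays or genes explain it, the cause was not tested.

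For LPS against PBS the count of 11 moved beyond 1.5 times in 25 of 28 fits, and stayed within it with quantile normalization (13) and median centring (9) on top and without the 2 PBS arrays of batch 2 (9, of which 0 were among the 11). It was 0 without the batch term, 0 with only the 2 groups, 4 with batch as a random block, 0 with the replicate number as a block (replicate block), and 40 within batch 2. It was 1 with no filter, 0 with a filter at the 60th percentile, 6 with the mean of the probe sets and 6 with every probe set, 3 without an intensity trend, 2 with robust variance, 826 with array weights and 3 with the Gapdh covariate. It was 5 without batch 2, 0 with the neuron mean as a covariate, 2 with values under log2 4 set to 4 (Cplx2 and Lrrn1, the latter named after its value was seen; 0 of the 11), and 0 by a plain test (343 unadjusted). With each array left out it ran from 0 to 120.

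For DAP12KO against UT the count of 0 held in 25 of 30 fits. It was 1 with the neuron mean as a covariate (Lonp2, named after its value was seen) and from 0 to 6 with each array left out. For the difference of the responses it held in 25 of 36. It was 271 within the batches with replicates, 1 with no filter, 1 with the mean of the probe sets, 1 with every probe set, 1 without an intensity trend (Snrnp25, but Tfap2c with every probe set, both named after their values were seen), 11 with array weights, and from 0 to 18 with each array left out.

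Signs turned for 19, 10 and 0 gene values and 1, 11 and 8 list values in the DAP12KO, the LPS and the difference comparison. For DAP12KO against UT these were small differences: without the batch term Csf1r −0.016, Itgam 0.20 and neuron markers 0.049, with a random block Csf1r −0.0078, with the mean of the probe sets Nusap1 −0.014, with median centring Itgam 0.039, with array weights Csf1r −0.012 and Itgam 0.047, and with the Gapdh covariate Itgam 0.043. With arrays left out they were, without DAP12KO replicate 1, Csf1r −0.0065; without replicate 4, Cx3cr1 0.072, Csf1r −0.031 and Itgam 0.15; without replicate 5, Itgam 0.13 and P2ry12 −0.041. Without UT replicate 2 of batch 4 they were Itgam 0.077 and P2ry12 −0.023, without replicate 3 Itgam 0.056, without replicate 6 Csf1r −0.00065, and with the neuron mean as a covariate Csf1r −0.049. With each array left out Cx3cr1 ran from −0.14 (without DAP12KO replicate 5) to 0.072, Csf1r from −0.031 to 0.068 (without DAP12KO replicate 5) and P2ry12 from −0.041 to 0.12 (without DAP12KO replicate 2). For LPS, both without batch 2 and without the 2 PBS arrays of batch 2, they were Tyrobp −0.081, Csf1r −0.019, Aif1 −0.071, Cd68 −0.11, Cd86 −0.39, and the lists DAP12 −0.29, TREM2-dependent −0.086, antigen presentation −0.23, phagocytosis −0.24 and chemokine receptors −0.30 (−0.23 with the neuron mean as a covariate). For the difference of the responses in the same 2 fits they were border macrophages −0.33, DAP12 −0.19, TREM2-dependent −0.077 and phagocytosis −0.077.

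Of other values, 1476 of 1732 for genes with LPS, 1186 of 1209 with DAP12KO and 335 of 356 for the difference kept direction and side of the threshold, as did 291 of 364, 131 of 168 and 207 of 280 for lists.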

Other observations

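The test of the genes around Tyrobp was written before the result was seen. DNA of another strain around the altered Tyrobp, carried over by crossing to C57BL/6, could change the expression of its neighbours on chromosome 7. Among the 100 tested genes nearest to Tyrobp, 13 had an unadjusted p under 0.05 in DAP12KO against UT (13%; 8 higher, 5 lower), against 5.40% of the other genes (Fisher's exact p = 0.00305). Of 1000 windows of 100 genes around random genes of other chromosomes, 3 reached 13, and the median of the windows was 5. The windows overlap and are not independent draws, so that 3 in 1000 is no p value. Fisher's exact test likewise takes neighbouring genes as independent. With LPS 8 of the 100 had an unadjusted p under 0.05, against 12.5% elsewhere (Fisher's exact p = 0.222). The lowest p among the neighbours belonged to Med29 (2.40), Lgi4 (1.81) and Gramd1a (−1.29), and 0 of the 100 passed over all genes, so that the excess is consistent with such DNA without naming a gene. Gene order was taken from the RefSeq table of assembly GRCm38.p6.

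Outside the LPS and PBS arrays, Xist was at 2.21 in UT replicate 6 of batch 4 and at 10.72 to 13.99 in the other UT and DAP12KO arrays (named after its values were seen).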
